A study of Nicotiana tabacum with 9 samples.

How the data were processed

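Leaf RNA of tobacco (Nicotiana tabacum) was sequenced in 9 libraries, 3 each of the plant materials labelled K326, Y and KY. Per the labels' protocols, total RNA was extracted with TRIzol, treated with DNase I and made into libraries with a TruSeq RNA kit, and these were sequenced as read pairs on an Illumina instrument. The labels give a replicate number to each library and do not say that replicates came from separate plants. The p-value of each single gene therefore measures the spread between these libraries, which may be partly technical. P-values from random draws of genes, used in some later tests, do not measure that spread. HISAT2, StringTie and RSEM are named, per the submitters' processing notes, without version, role or order, and the genome build and counting settings are not given in the sources used here.

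The authors deposited 1 table with an expression signal for each of 69500 genes of the Nitab4.5 gene set in each library, together with the mean of each material. The deposited signal is never negative, has at most 2 decimals and is not named as a unit in the file headers. It adds up to different totals per library, so it is neither a raw count nor a value scaled to a fixed total over the listed genes. Each of the authors' 3 mean columns equalled the mean of its libraries within 3.33e-06, and the means were not used further. The table pairs each gene identifier with protein domain descriptions, and 19827 genes are described as Unknown. The gene names used here are those descriptions. A reference table of 79372 tobacco genes (assembly ASM71507v2) shared 0 identifiers with the deposited table, so no symbols or coordinates are given.

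The signal summed to 551496 in K326 replicate 1, the lowest library, and to 603165 in KY replicate 1, the highest, and 30510 to 33397 genes were above 0. Read depth is unknown. The relative worth of 1 read was estimated as the most frequent ratio of a library's values to those of K326 replicate 1. Genes above 0 in at most 4 libraries, with values of at least 0.15 in both libraries, were used. The estimate ranged from 1 in K326 replicate 1, the reference, to 1.32 in K326 replicate 2. It rests on 199 to 364 genes per library, has no interval and also depends on expression, so it sets no firm bound on relative depth. No interval that needs read numbers is given. Tobacco is an allotetraploid that carries near-identical copies of many genes, and values of such copies depend on how reads were divided between them. Values of single copies, and of single members of histone or light-harvesting families, are therefore uncertain.

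The design fixed before the data were examined foresaw a count-based test if counts were given. The deposited table holds no counts, so the planned test for other units was used. Values were transformed as log2(value + 1), with a pseudocount of 1, and 16348 genes with a mean of at least 1 over the 9 libraries were tested. All 9 libraries entered 1 model with a mean per material, fitted with limma 3.58.1 in R 4.3.3 (empirical Bayes with a mean-variance trend), and p-values were adjusted by the Benjamini-Hochberg method. A gene was called at an adjusted p below 0.05, and calls with an absolute log2 difference of at least 1 were counted as well. Every log2 difference is on the log2(value + 1) scale, which understates the change of genes with low values. The contrasts were Y minus K326, KY minus K326, KY minus Y, and KY minus the mean of K326 and Y.

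Gene lists were defined before the data were examined by patterns matched to the descriptions. Of 40 lists, 31 had at least 5 tested genes, 4 had fewer and 5 matched no gene. Each was compared with the other tested genes by limma's camera test with a preset correlation of 0.01 and Benjamini-Hochberg adjustment over the 31 lists. Beside it, camera with an estimated correlation and fry were run. With the preset correlation, camera compares genes with genes as nearly independent units, so its p-values do not measure the spread between libraries. Descriptions name protein domains, so that some lists hold more than their title: the dividing-cell list is mostly core histones, and the flower and pollen list is mostly expansins and extensin-domain proteins.

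Named genes follow a rule fixed before the data were examined. It took every tested dihydroneopterin aldolase gene. It also took, per comparison, the 5 highest and 5 lowest log2 differences among called genes with an informative description, a mean of at least 5 in the higher material and replicates that did not overlap. It further took the 2 called members with the smallest adjusted p from each focal list and from up to 8 other lists past the camera test. This gave 22, 17 and 15 genes for Y minus K326, KY minus K326 and KY minus Y. Other list members appear as values beside the count of their list, and genes chosen after their values were seen are marked as such.

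The procedure was tested on simulated data with 200 changed genes among 16348. For Y minus K326, 36% of genes changed 2-fold, 76% of those changed 4-fold and 84% of those changed 8-fold were called in the right direction, with 7 false calls among the unchanged genes. For KY minus K326 the shares were 30%, 70% and 86%, with 6 false calls, and for KY minus Y 38%, 80% and 82%, with 12. Of genes changed 1.5-fold, 2%, 0% and 4% were called in these contrasts, in the same order, so changes of that size are mostly missed. The simulated noise was independent between genes, which real genes are not.

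Other settings named before the data were examined were pseudocounts of 0.1 and 5, no filter on low values, a fit of only the groups compared, a replicate block, the leaving out of each library in turn, camera with an estimated correlation, and fry. Median-of-ratios scaling, scaling to a fixed total, quantile normalization, a mean of at least 5 and robust empirical Bayes were added after the data were seen. Settings that need counts were not run because the table holds none. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.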

Results

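Transcript levels were measured by RNA sequencing in tobacco leaf tissue from 3 plant materials, labelled K326, Y and KY, with 3 libraries each. K326 is a cultivar of flue-cured tobacco. The labels do not say what Y and KY are, and no meaning is assumed here. The title of the series names leaf yellowing and a folate-synthesis gene written DHNA, so genes of folate, chlorophyll, carotenoids and photosynthesis were followed as focal lists. A focal list of senescence-associated genes matched no description, so senescence could not be tested as a list. The deposited signal summed to between 551496 and 603165 per library, and read depth is unknown. Pearson correlations of log2(value + 1) across the tested genes ranged from 0.899 to 0.964 between libraries of the same material and from 0.897 to 0.954 between materials; genes are not independent replicates. KY replicate 1 stood apart from the other KY libraries. The library it correlated with best was K326 replicate 3 (r = 0.954), and K326 replicate 3 in turn correlated best with KY replicate 1.

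The gene described as dihydroneopterin aldolase (Nitab4.5_0008674g0010), an enzyme of folate synthesis, had values of 15.3, 19.5 and 9.09 in the 3 K326 libraries and was listed at 0 in all 3 Y libraries and all 3 KY libraries. Its log2(value + 1) level was lower than in K326 by the same amount in Y (-3.91, SE 0.25, limma adjusted p = 3.71e-05) and in KY (-3.91, SE 0.25, limma adjusted p = 5.87e-05). The call held under every alternative setting in which the gene was tested, 18 for each comparison. Another gene with this description, Nitab4.5_0000677g0080, was listed at 0 in all 9 libraries and was not tested. The same holds for Nitab4.5_0000936g0150, described only by a dihydroneopterin aldolase/epimerase domain. The same direction in Y and KY is not independent evidence, since both were compared with the same K326 libraries. A listed 0 in this table does not exclude transcripts, because read depth is unknown.

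**Figure D1:**
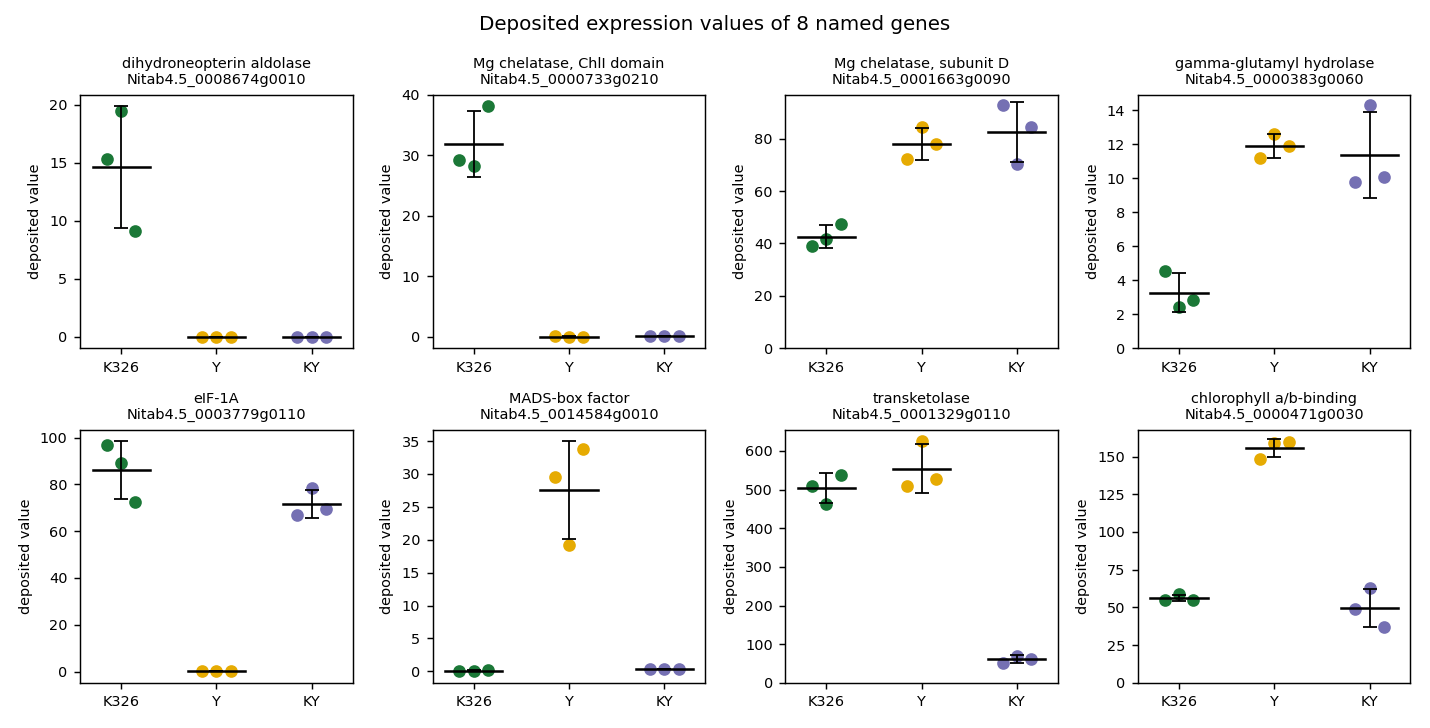
Deposited values (vertical axes, linear and starting near 0) of 8 named genes in the libraries of K326, Y and KY; points are libraries, horizontal bars are means and error bars are SD (n = 3). Dihydroneopterin aldolase was listed at 0 in all Y and KY libraries, and transketolase had a mean of 61.5 in KY against 504 in K326 and 554 in Y.

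Comparing Y with K326 asks which transcripts separate these materials. In Y leaves, a MADS-box transcription factor gene rose from near 0, while an E2 ubiquitin-conjugating enzyme gene and a translation initiation factor gene fell to near 0. Light-harvesting genes stood higher as a group, and the dividing-cell list, mostly histones, stood lower, by camera with a preset correlation (adjusted p = 0.543 with an estimated correlation for both). In total 127 genes rose and 198 fell among the 16348 tested (limma, Benjamini-Hochberg adjusted p below 0.05), of which 111 and 173 changed at least 2-fold. The MADS-box gene (Nitab4.5_0014584g0010), of a family of developmental regulators, rose from 0.093 ± 0.083 in K326 to 27.5 ± 7.47 in Y (SD, n = 3; log2 difference 4.67, SE 0.21, limma adjusted p = 4.06e-06). The E2 gene (Nitab4.5_0003779g0060) fell from 97.8 ± 13.9 to 0.233 ± 0.105 (log2 difference -6.32, SE 0.19, limma adjusted p = 5.81e-07). The gene for eIF-1A (Nitab4.5_0003779g0110), a factor that helps the ribosome find the start codon, fell from 86.0 ± 12.5 to 0.227 ± 0.117 (log2 difference -6.14, SE 0.16, limma adjusted p = 4.12e-07). A CRAL-TRIO lipid-binding domain gene (Nitab4.5_0000976g0100) had values of 42.7, 35.5 and 43.3 in K326 and was listed at 0 in all 3 Y libraries (limma adjusted p = 4.12e-07). Among the other large rises were a small heat shock protein gene (Nitab4.5_0000278g0020; 1.03 to 22.5), a DnaJ domain gene (Nitab4.5_0005707g0010; 0.69 to 28.2), a family 18 chitinase gene (Nitab4.5_0000416g0250; 0.03 to 16.4) and an NB-ARC disease resistance gene (Nitab4.5_0021935g0010; 0.003 to 8.19). Another small heat shock protein gene (Nitab4.5_0000008g0240) fell from 56.2 to 0.183. This call was lost in 9 of 19 alternatives, among them the omission of any 1 K326 or Y library (limma adjusted p from 0.0822 to 0.107). The DnaJ call was lost without K326 replicate 2 or 3 or Y replicate 1 (limma adjusted p from 0.0538 to 0.0582). The chitinase call was lost without any 1 K326 library (limma adjusted p from 0.0503 to 0.0527).

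Of 8 tested genes in the folate biosynthesis list, 1 rose in Y and 1 fell, and the counts adjusted over the list alone were 1 and 1. The fall was dihydroneopterin aldolase. The rise was a gamma-glutamyl hydrolase gene (Nitab4.5_0000383g0060), whose enzyme trims the glutamate tail of folates, from 3.25 ± 1.14 to 11.9 ± 0.695 (SD, n = 3; log2 difference 1.63, SE 0.22, limma adjusted p = 0.0051). Both GTP cyclohydrolase I genes, which encode the entry enzyme of the pathway, stayed below the threshold, with means of 10.3 in K326 and 9.25 in Y for Nitab4.5_0002671g0010 and of 10.6 and 9.07 for Nitab4.5_0003020g0100. One member, Nitab4.5_0012814g0010, is described as an enzyme of isoprenoid synthesis with a dihydropteroate synthase-like domain. As a group the list showed no shift in a common direction against the other genes (camera adjusted p = 0.871). Fry's mixed test, which asks for change in either direction within the list, passed (fry mixed adjusted p = 2.67e-06).

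Single chlorophyll genes moved in both directions. Of 28 chlorophyll biosynthesis genes, 1 rose and 1 fell, with counts of 1 and 1 adjusted over the list alone, and the list did not pass the camera test (adjusted p = 0.132), though it did without K326 replicate 3 (camera adjusted p = 0.000758). Both were magnesium chelatase genes, whose enzyme inserts magnesium into protoporphyrin. Both descriptions hold a von Willebrand factor type A domain and a ChlI subunit entry, so these genes may be related copies. Whether 1 copy stands in for the other was not tested. In deposited values, the fall of 1 gene was about as large as the rise of the other, as given next. Their calls therefore need not mean opposite changes of the pathway. The ChlI-domain gene Nitab4.5_0000733g0210 fell from 31.9 ± 5.42 to 0.013 ± 0.015 (log2 difference -5.01, SE 0.16, limma adjusted p = 9.42e-07). The subunit D gene Nitab4.5_0001663g0090 rose from 42.6 ± 4.32 to 78.2 ± 6.1 (log2 difference 0.86, SE 0.15, limma adjusted p = 0.0254). This call was lost in 8 of 19 alternatives, among them the omission of any 1 K326 or Y library or of KY replicate 3 (limma adjusted p from 0.0552 to 0.123). In the chlorophyll breakdown list of 18 genes, a pheophorbide a oxygenase-type gene (Nitab4.5_0002162g0210) rose from 30.5 to 74.3 and another (Nitab4.5_0003134g0120) fell from 3.51 to 0.01, and the counts were again 1 and 1 adjusted over the list alone. The first of these calls was lost in 5 of 19 alternatives, among them the omission of K326 replicate 2 or 3 or of Y replicate 1 or 2 (limma adjusted p from 0.0636 to 0.0785). The list did not pass (camera adjusted p = 0.111) except without K326 replicate 1 or 3 (camera adjusted p = 0.0262 and 0.0232) and with a mean of at least 5 (camera adjusted p = 0.021).

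The 72 light-harvesting antenna genes, which encode the chlorophyll-binding proteins around the photosystems, were shifted upward in Y, with 59 above and 12 below 0 and a median log2 difference of 0.23 against -0.08 over all tested genes (camera adjusted p = 2.05e-09; adjusted p = 0.543 with an estimated correlation). Only 1 of them rose, Nitab4.5_0000471g0030, from 56.2 ± 2.27 to 156 ± 6.05 (SD, n = 3; limma adjusted p = 0.00358), and the count was 1 adjusted over the list alone. The photosystem subunit list also passed (29 genes, median 0.09, camera adjusted p = 0.0425), with 0 members called by limma, 0 adjusted over the list alone, and 2 up and 1 down at an unadjusted p below 0.05 (adjusted p = 0.543 with an estimated correlation). It was lost in 10 of 19 alternatives, among them the omission of K326 replicate 1 or 2, Y replicate 1 or 2, or KY replicate 3 (camera adjusted p from 0.0533 to 0.302). Its median was 0.01 without K326 replicate 2, 0.06 without Y replicate 2, and 0.20 or 0.21 without K326 replicate 3 or Y replicate 3. Neither the Calvin cycle list (28 genes, median -0.001, camera adjusted p = 0.234) nor carotenoid biosynthesis (14 genes, median 0.02, camera adjusted p = 0.398) passed in Y. Both had 0 members called by limma, and 1 Calvin cycle gene rose adjusted over the list alone. The auxin response list stood higher (77 genes, median 0.29, camera adjusted p = 0.0112; adjusted p = 0.543 with an estimated correlation), with 1 member up and 1 down by limma, or 2 and 1 adjusted over the list alone. These were 2 auxin efflux carrier genes, Nitab4.5_0000464g0020, which rose from 2.91 to 17.7, and Nitab4.5_0007384g0040, which fell from 3.24 to 0.067. The list was lost without a filter on low values, where its median was 0.01 (camera adjusted p = 0.235), and without Y replicate 1 (camera adjusted p = 0.0763), and its median was 0.12 without K326 replicate 3. Likewise without Y replicate 2 the rise of the first carrier was lost (limma adjusted p = 0.0526). The autophagy list stood higher with 0 of 27 members called by limma, 0 adjusted over the list alone, and 3 up at an unadjusted p below 0.05 (median 0.14, camera adjusted p = 0.0298; adjusted p = 0.563 with an estimated correlation). It was lost without a filter on low values (camera adjusted p = 0.0652) and without K326 replicate 3 or Y replicate 3 (medians 0.09 and 0.08, camera adjusted p = 0.14 and 0.151).

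Genes of dividing cells stood lower in Y, with 99 of 106 members below 0 and a median log2 difference of -1.03 (camera adjusted p = 5.97e-18; adjusted p = 0.543 with an estimated correlation). In this list 6 genes fell and 0 rose, and 21 fell adjusted over the list alone. A histone H2A gene (Nitab4.5_0008504g0010) had values of 71.5, 47.8 and 113 in K326 and was listed at 0 in all 3 Y libraries, and a histone H2B gene (Nitab4.5_0001163g0030) fell from 19.6 ± 0.837 to 0.07 ± 0.07. The mean of this list differed between libraries of 1 material as well. Relative to its mean over the 9 libraries it was 0.63, 0.21 and 1.06 log2 units in K326 replicates 1 to 3, and -0.41, -0.17 and -0.71 in Y replicates 1 to 3. The cytosolic ribosome list also stood lower (25 genes, 24 below 0, median -0.42, camera adjusted p = 0.00688; adjusted p = 0.759 with an estimated correlation). Its only called member, also the only one adjusted over the list alone, was a 60S ribosomal protein L18a gene (Nitab4.5_0002000g0060), which fell from 40 to 0.17. Like the H2A and H2B genes above, L18a was near 0 in all Y libraries. Such genes are described below, and why they were near 0 stays open. The ribosome list was lost without K326 replicate 3 or Y replicate 3 (camera adjusted p = 0.111 and 0.218), and its median was -0.27 without Y replicate 3 and -0.65 without Y replicate 2. The flower and pollen list stood lower (47 genes, median -0.40, camera adjusted p = 0.0116; adjusted p = 0.544 with an estimated correlation), with 1 expansin gene (Nitab4.5_0010278g0040) falling from 7.65 to 4.05, or 1 up and 1 down adjusted over the list alone. That list was lost without Y replicate 3 (camera adjusted p = 0.0985). The expansin call was lost in 18 of 19 alternatives, among them the omission of any 1 library except KY replicate 1 (limma adjusted p from 0.0674 to 0.198).

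The total of 325 called genes became 191, 195 or 189 without K326 replicate 1, 2 or 3, and 176 or 194 without Y replicate 1 or 2, each time for the same comparison of Y with K326. The median over all tested genes was -0.08, and the split of 127 up and 198 down became 146 and 170 under median-of-ratios scaling and 153 and 174 under quantile normalization.

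**Figure D2:**
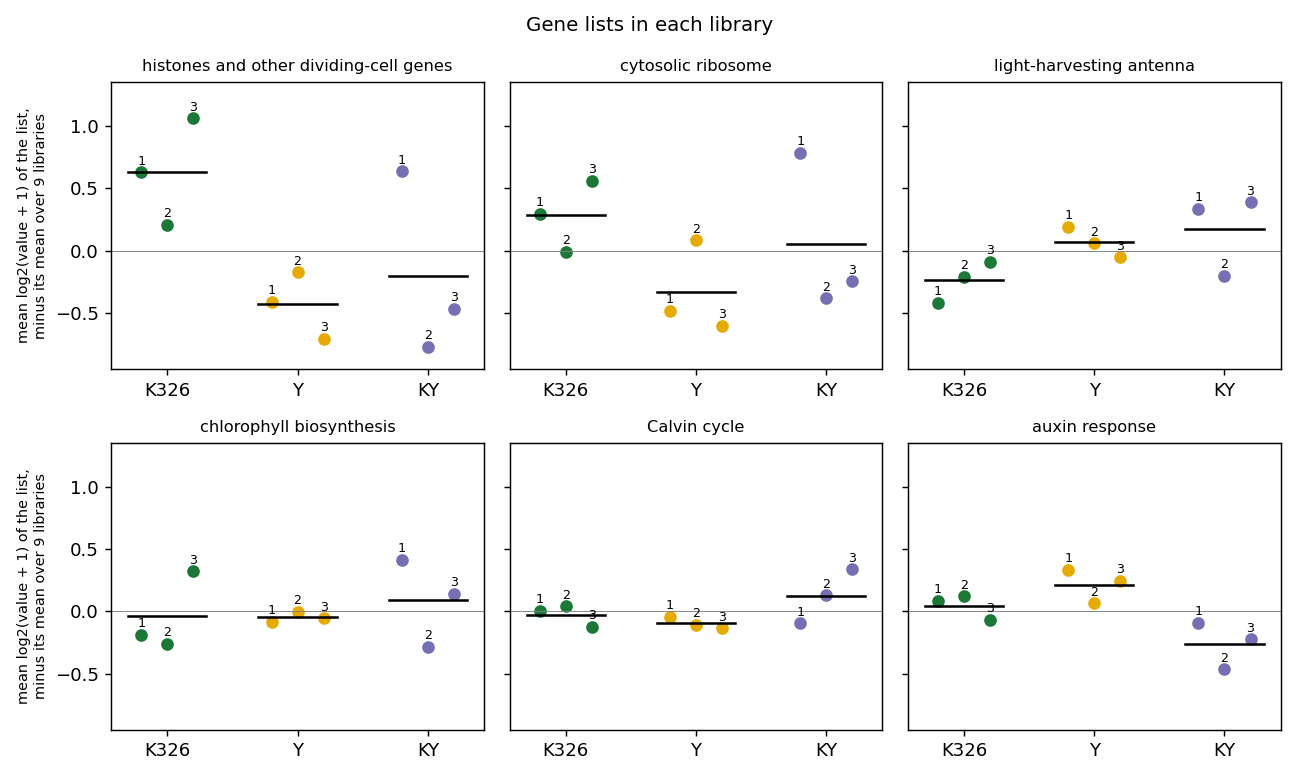
Mean log2(value + 1) of 6 gene lists in each library, minus the mean of the list over the 9 libraries (vertical axis, log2 units); numbers beside points are replicate numbers and bars are means of the 3 libraries. In the dividing-cell list KY replicate 1 lies at 0.64, near the K326 libraries, and KY replicates 2 and 3 lie at -0.77 and -0.47.

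Comparing KY with K326 asks how the remaining material differs from the same cultivar. In KY leaves, 2 lectin domain genes and an NB-ARC disease resistance gene rose, the ChlI-domain magnesium chelatase gene and the CRAL-TRIO gene fell to near 0 as they did in Y, and light-harvesting, photosystem, Calvin cycle and chlorophyll biosynthesis genes stood higher as groups, by camera with a preset correlation (adjusted p from 0.492 to 0.56 with an estimated correlation). A transketolase gene that the Calvin cycle list does not hold was far lower in KY (means of 504 in K326 and 61.5 in KY). In total 38 genes rose and 91 fell (limma, Benjamini-Hochberg adjusted p below 0.05), of which 34 and 84 changed at least 2-fold. Among the large rises were a mannose-binding lectin gene (Nitab4.5_0002977g0130), from 0.237 ± 0.208 in K326 to 6.93 ± 1.03 in KY (SD, n = 3; log2 difference 2.69, SE 0.20, limma adjusted p = 0.000189), and the NB-ARC resistance gene Nitab4.5_0021935g0010, from 0.003 to 5.69. A gene for a PC4-type transcriptional coactivator (Nitab4.5_0001310g0060) rose from 14.7 ± 2.46 to 100 ± 26.0 (log2 difference 2.66, SE 0.23, limma adjusted p = 0.000429). A ricin B lectin domain gene (Nitab4.5_0000571g0030) rose from 4.57 to 26.1 and an actin-depolymerizing cofilin gene (Nitab4.5_0008504g0030) from 11.5 to 53. The CRAL-TRIO gene Nitab4.5_0000976g0100 fell from 40.5 ± 4.35 to 0.02 ± 0.017 (log2 difference -5.34, SE 0.15, limma adjusted p = 8.63e-07). The magnesium chelatase gene Nitab4.5_0000733g0210 fell from 31.9 to 0.043 (log2 difference -4.97, SE 0.16, limma adjusted p = 2.03e-06). The subunit D gene Nitab4.5_0001663g0090 rose from 42.6 to 82.6 (log2 difference 0.93, SE 0.15, limma adjusted p = 0.0349). This call was lost in 9 of 19 alternatives, among them the omission of any 1 K326 or Y library or of KY replicate 3 (limma adjusted p from 0.0596 to 0.185). An NAD(P)-binding domain gene (Nitab4.5_0000102g0310) fell from 68.3 to 1.70, and a mitochondrial carrier gene of the uncoupling protein type (Nitab4.5_0010196g0040) fell from 29.7 to 0.503. An ascorbate peroxidase gene (Nitab4.5_0011292g0010) was at 26.6, 26.1 and 20.1 in K326 and was listed at 0 in all 3 KY libraries. The limma adjusted p was 0.0483, and the call was lost in 15 of 19 alternatives, among them the omission of any 1 library except Y replicate 2 or KY replicate 1 (limma adjusted p from 0.0513 to 0.202). All materials share 1 estimate of the spread in this model, and the Y libraries of this gene were at 0, 11.8 and 0. When only KY and K326 were fitted, the call was kept.

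In the folate list, 1 of 8 genes rose and 1 fell in KY, with counts of 1 and 1 adjusted over the list alone, and these were again gamma-glutamyl hydrolase (3.25 to 11.4, limma adjusted p = 0.0129) and dihydroneopterin aldolase. The hydrolase call was lost in 5 of 19 alternatives, among them the omission of K326 replicate 2 or 3 or KY replicate 3 (limma adjusted p from 0.0503 to 0.075). The list as a whole showed no shift in a common direction against the other genes (camera adjusted p = 0.84), while fry's mixed test passed (fry mixed adjusted p = 3.76e-06). In the chlorophyll breakdown list, the oxygenase-type gene Nitab4.5_0003134g0120 fell from 3.51 to 0.03, the only call among 18 genes, and the counts were 1 up and 1 down adjusted over the list alone. The call was lost with a pseudocount of 0.1 (limma adjusted p = 0.0631). That list did not pass (camera adjusted p = 0.0972) except without any 1 K326 library or KY replicate 1 (camera adjusted p from 0.0147 to 0.031) and with a mean of at least 5 (camera adjusted p = 0.000111).

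Of the photosynthesis lists, light-harvesting, photosystem subunits and the Calvin cycle stood higher in KY than in K326, but not in every library. Electron transport and photorespiration did not pass (5 and 12 genes, camera adjusted p = 0.225 for both). Relative to the mean over the 9 libraries, the light-harvesting list was at 0.34, -0.20 and 0.39 log2 units in KY replicates 1 to 3 and at -0.42, -0.21 and -0.09 in K326, so KY replicate 2 lay within the range of K326. The chlorophyll biosynthesis list was at 0.41, -0.29 and 0.14 in KY, where replicate 2 was the lowest of the 9 libraries, and at -0.19, -0.26 and 0.32 in K326. The Calvin cycle list was at -0.10 in KY replicate 1, within the range of K326 (-0.12 to 0.04). Among 72 light-harvesting genes, 60 lay above 0, with a median log2 difference of 0.25 against -0.14 over all tested genes (camera adjusted p = 2.71e-19; adjusted p = 0.492 with an estimated correlation). In this list 2 genes rose, or 8 adjusted over the list alone: Nitab4.5_0000592g0370 went from 121 ± 24 to 306 ± 79.2 and Nitab4.5_0002210g0110 from 22.1 ± 3.6 to 54.6 ± 13.8 (SD, n = 3). These calls were lost in 6 and 10 of 19 alternatives. The first was lost without K326 replicate 1 or 2, Y replicate 1 or 2, or KY replicate 3 (limma adjusted p from 0.0542 to 0.131). The second was lost without any 1 K326 or Y library or KY replicate 3 (limma adjusted p from 0.0671 to 0.202). The median of the light-harvesting list was 0.16 or 0.39 without K326 replicate 1 or 3 and 0.44 without KY replicate 2.

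The chlorophyll biosynthesis list passed in KY minus K326 as well (28 genes, 19 above 0, median 0.21, camera adjusted p = 1.67e-05; adjusted p = 0.56 with an estimated correlation), with 1 member up and 1 down, or 2 and 1 adjusted over the list alone. Its median was 0.04 or 0.38 without K326 replicate 2 or 3, and 0.11 or 0.41 without KY replicate 1 or 2. The Calvin cycle list passed (28 genes, 23 above 0, median 0.09, camera adjusted p = 4.48e-05; adjusted p = 0.492 with an estimated correlation). This list was lost under quantile normalization (camera adjusted p = 0.0942), and its median was 0.19 or 0.03 without KY replicate 1 or 3. Its only called member, and the only one adjusted over the list alone, was a gene for the rubisco small subunit, part of the carbon-fixing enzyme (Nitab4.5_0000912g0250), which rose from 987 ± 24.2 to 1968 ± 209 (limma adjusted p = 0.0361). This call was lost in 10 of 19 alternatives, among them the omission of any 1 K326 library, Y replicate 1, or KY replicate 2 or 3 (limma adjusted p from 0.0821 to 0.176). Transketolase, which also acts in the Calvin cycle, is not in the list. Its gene Nitab4.5_0001329g0110 had means of 504 in K326 and 61.5 in KY, so the shift of the list does not hold for every gene of the cycle.

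Photosystem subunits (29 genes, median 0.11, camera adjusted p = 0.00229; adjusted p = 0.526 with an estimated correlation), carotenoid biosynthesis (14 genes, median 0.11, camera adjusted p = 0.0164; adjusted p = 0.526 with an estimated correlation) and folate one-carbon metabolism (16 genes, median 0.10, camera adjusted p = 0.017; adjusted p = 0.492 with an estimated correlation) stood higher in KY with 0 members called by limma and 0 adjusted over the list alone. At an unadjusted p below 0.05 the photosystem list had 1 member up, the carotenoid list 2 up and 1 down, and the one-carbon list 1 up. Without K326 replicate 1 these lists were lost (camera adjusted p = 0.0667, 0.138 and 0.0667). Without KY replicate 2 the carotenoid and one-carbon lists were (camera adjusted p = 0.064 and 0.3). Quantile normalization ended the photosystem and carotenoid calls (camera adjusted p = 0.0612 for both), a mean of at least 5 the carotenoid call (camera adjusted p = 0.0634), and no filter on low values the one-carbon call (camera adjusted p = 0.0608). The photosystem median was 0.01 without KY replicate 1, and 0.07, 0.05 or 0.19 without K326 replicate 1, 2 or 3. The carotenoid median was 0.06 or 0.04 without K326 replicate 1 or 2 and 0.06 without KY replicate 3. The one-carbon median was 0.15 or 0.16 without KY replicate 1 or 3.

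The dividing-cell list stood lower in KY than in K326 (102 of 106 below 0, median -0.78, camera adjusted p = 4.28e-10; adjusted p = 0.691 with an estimated correlation), with 0 members called by limma, 0 adjusted over the list alone, and 37 down at an unadjusted p below 0.05. Within KY it differed by library, at 0.64 in replicate 1 and at -0.77 and -0.47 in replicates 2 and 3. Without KY replicate 1, 39 of its genes were called lower by limma and the median was -1.19 (camera adjusted p = 1.47e-18), and the cytosolic ribosome list also passed (median -0.65, camera adjusted p = 0.00166). Genes of abscisic acid and dehydration responses (64 genes, median -0.40, camera adjusted p = 0.0173; adjusted p = 0.526 with an estimated correlation) and of the flower and pollen list (47 genes, median -0.40, camera adjusted p = 0.024; adjusted p = 0.691 with an estimated correlation) stood lower, with 0 members called in either by limma, 0 adjusted over the list alone, and 12 and 8 down at an unadjusted p below 0.05, besides 1 flower and pollen gene up. The first was lost without a filter on low values (camera adjusted p = 0.179) and without K326 replicate 2 or KY replicate 1 (camera adjusted p = 0.0573 and 0.104). The second was lost when only KY and K326 were fitted (camera adjusted p = 0.0576) and without K326 replicate 2 or 3 or KY replicate 2 (camera adjusted p from 0.0741 to 0.33). Without KY replicate 1 the members called lower by limma were 4 and 8. The fall of abscisic acid and dehydration genes was not particular to KY. In Y minus K326 their median was -0.33 and the list did not pass (camera adjusted p = 0.0643). There 7 members were called lower and 0 higher by limma, or 11 lower and 5 higher adjusted over the list alone. The flower and pollen median was -0.62 without KY replicate 1 and -0.24 without KY replicate 2.

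The median log2 difference of KY from K326 over all tested genes was -0.14, and median-of-ratios scaling moved it to -5e-04. Under that scaling 49 genes rose and 71 fell, and under quantile normalization 51 and 73, against 38 and 91 as reported. Without KY replicate 1 the count became 646 genes, 100 up and 546 down, which included 127 of the 129. Without K326 replicate 1, 2 or 3 it became 70, 69 or 76, and without KY replicate 3 it became 78.

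Genes called in both comparisons with K326 changed the same way in 90 cases, 28 up and 62 down, and in opposite ways in 1. Dihydroneopterin aldolase, the ChlI-domain magnesium chelatase gene, the CRAL-TRIO gene, gamma-glutamyl hydrolase and the NB-ARC gene were among the 90. The opposite case, chosen after its values were seen, was a G-box-binding bZIP transcription factor gene (Nitab4.5_0002262g0160) with means of 9.27 in K326, 28.5 in Y and 3.37 in KY. Independent lists of these sizes would share 0.295 rising and 1.10 falling genes. In 100 simulated sets without effects that shared their K326 libraries, the mean overlap was 0.01 and the highest was 1. Without effects few genes can be called in either comparison, so an overlap near 0 was fixed in advance. It does not show how much overlap the shared K326 libraries give where real differences exist. The log2 differences from K326 correlated at 0.498 across genes, against 0.499 in the simulations, and their covariance was 0.127 against 0.0536, a difference of 0.073. Because 3 control libraries cannot be split into parts of at least 2, part of the overlap may come from the shared controls. Without KY replicate 1 the overlap was 180 genes.

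**Figure D3:**
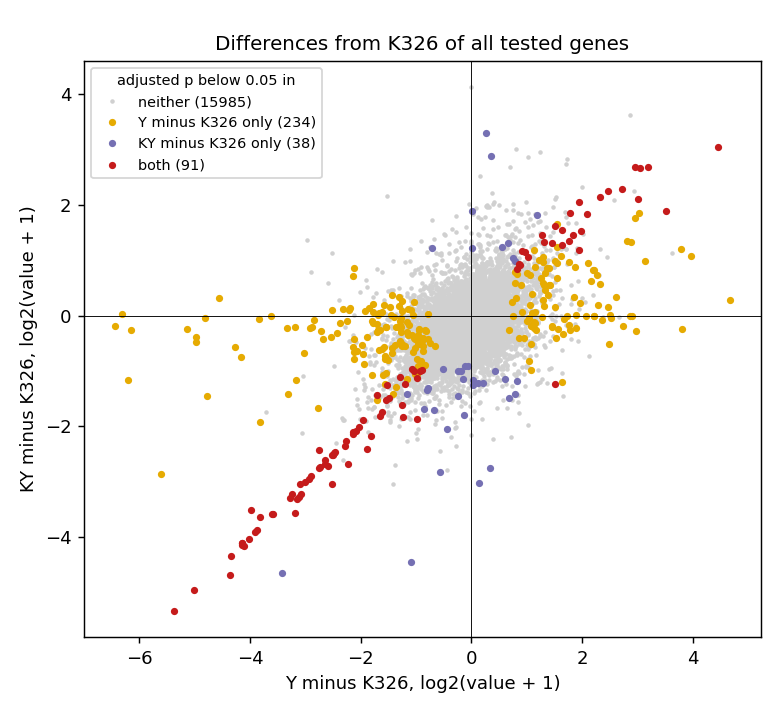
Log2(value + 1) differences of Y minus K326 (horizontal axis) and KY minus K326 (vertical axis) for the 16348 tested genes, coloured by the comparison in which the adjusted p was below 0.05. Of the genes called in both, 90 lie in the quadrants of the same direction and 1 in that of opposite directions.

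Among the 325 genes called between Y and K326, the mean log2 level in KY lay between those of Y and K326 for 215, above both for 42 and below both for 68. Genes chosen because Y and K326 lie apart favour a place between them. In 50 simulations each with KY set equal to K326 or to Y in every gene, and genes independent, 54.8% and 54.3% lay between on average. The highest shares were 60.4% and 63.4%, and the measured 66.2% lay above both. Real genes are not independent, and a KY equal to K326 in some genes and to Y in others was not simulated. The count of 215 therefore does not decide whether KY is intermediate. Among the 325 genes, KY differed from K326 but not past the threshold from Y in 90. It differed from Y but not past the threshold from K326 in 110, from both in 1 and from neither in 124. In the group that differed from Y were the E2 gene, at 97.8 in K326 and 101 in KY, and the eIF-1A gene, at 86.0 and 71.6. In the group that differed from K326 was dihydroneopterin aldolase, listed at 0 in both Y and KY.

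Comparing KY with Y asks where these materials part. The E2 gene, the eIF-1A gene, an aminotransferase gene and histone genes that were near 0 in Y were present in KY, while the MADS-box gene and a transketolase gene were far lower in KY. In total 79 genes rose and 133 fell in KY relative to Y (limma, Benjamini-Hochberg adjusted p below 0.05), of which 77 and 126 changed at least 2-fold. The E2 gene Nitab4.5_0003779g0060 was higher in KY, at 101 ± 20.6 against 0.233 ± 0.105 (SD, n = 3; log2 difference 6.35, SE 0.19, limma adjusted p = 8.28e-07), and a class III aminotransferase gene (Nitab4.5_0002232g0040) at 29.6 ± 5.64 against 0.11 ± 0.121 (log2 difference 4.78, SE 0.19, limma adjusted p = 4.38e-06). The eIF-1A gene Nitab4.5_0003779g0110 differed by 5.89 log2 units and the ribosomal protein L18a gene Nitab4.5_0002000g0060 by 4.89. Transketolase (Nitab4.5_0001329g0110), an enzyme of carbon metabolism, fell from 554 ± 63.5 in Y to 61.5 ± 9.53 in KY (log2 difference -3.16, SE 0.15, limma adjusted p = 1.62e-05). The MADS-box gene Nitab4.5_0014584g0010 fell from 27.5 to 0.337 and the mitochondrial carrier gene Nitab4.5_0010196g0040 from 14.1 to 0.503. A flavin amine oxidase gene (Nitab4.5_0007665g0030) fell from 11 to 0.327 and a late embryogenesis abundant protein gene (Nitab4.5_0008334g0040), of a family linked to water loss, from 11.7 to 0.317. The amine oxidase call was lost with a pseudocount of 0.1 (limma adjusted p = 0.0573). The last call was lost without Y replicate 2 or KY replicate 3 (limma adjusted p = 0.0536 and 0.0706).

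The auxin response list stood lower in KY than in Y (77 genes, 59 below 0, median -0.53, camera adjusted p = 0.00011; adjusted p = 0.838 with an estimated correlation), with 2 members down, or 10 adjusted over the list alone. The list was lost without a filter on low values, where its median was -0.06 (camera adjusted p = 0.1). Both called members are small auxin-induced ARG7-type genes. Nitab4.5_0008453g0010 fell from 15.7 ± 3.14 to 5.08 ± 0.712 and Nitab4.5_0000307g0200 from 14.4 ± 1.16 to 7.57 ± 0.482 (SD, n = 3). These calls were lost in 5 and 14 of 19 alternatives. The first was lost without Y replicate 1 or 2 or KY replicate 2 or 3 (limma adjusted p from 0.0657 to 0.115). The second was lost without any 1 library except K326 replicate 3 (limma adjusted p from 0.062 to 0.179). In the light-harvesting list, which did not pass the test (camera adjusted p = 0.0612), Nitab4.5_0000471g0030 fell from 156 ± 6.05 to 49.7 ± 12.8 (limma adjusted p = 0.00237), the only call, and also the only one adjusted over the list alone. The folate and chlorophyll biosynthesis lists had 0 members called by limma and 0 adjusted over the list alone (camera adjusted p = 0.72 and 0.0612). Here 1 folate gene was down, and 1 chlorophyll gene up and 1 down, at an unadjusted p below 0.05. The light-harvesting list passed without K326 replicate 1 or 3, Y replicate 1 or KY replicate 2 (camera adjusted p from 3.34e-06 to 0.0406). Chlorophyll biosynthesis passed without K326 replicate 3, Y replicate 1 or 2, or KY replicate 2 (camera adjusted p from 0.000915 to 0.0334), and with a replicate block (camera adjusted p = 0.0448). The Calvin cycle list did not pass (camera adjusted p = 0.0612), except without K326 replicate 3, Y replicate 1 or KY replicate 1 (camera adjusted p from 0.000564 to 0.0334) and in the fits that follow. When only KY and Y were fitted these 3 lists passed (camera adjusted p = 0.0341 for each), and with a mean of at least 5 they did too (camera adjusted p = 0.0101 for light-harvesting, 0.0197 for chlorophyll biosynthesis and 0.0171 for the Calvin cycle).

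The dividing-cell list stood higher in KY than in Y (65 of 106 above 0, median 0.07, camera adjusted p = 0.00219; adjusted p = 0.838 with an estimated correlation), and 3 histone genes rose, or 3 adjusted over the list alone. Histone H2A gene Nitab4.5_0008504g0010 was listed at 0 in all Y libraries and was at 78.8, 17.1 and 24 in KY replicates 1 to 3, and histone H2B gene Nitab4.5_0001163g0030 was at 31.2, 6.39 and 10.4 there. The last of the 3, Nitab4.5_0027235g0010, chosen after its values were seen, had means of 0.023 and 11.3. The cytosolic ribosome list stood higher with it (23 of 25 above 0, median 0.21, camera adjusted p = 0.0132, and adjusted p = 0.838 with an estimated correlation), with L18a its only call and the only one adjusted over the list alone. The 3 histone genes and L18a were all near 0 in Y. Such genes are described below, and why they were near 0 stays open, so these calls alone do not show a shift of either list. Without KY replicate 1 the median of the dividing-cell list was -0.24 and neither list passed (camera adjusted p = 0.908 for both), and without Y replicate 3 neither passed (camera adjusted p = 0.375 and 0.445). The dividing-cell median was 0.23 or 0.04 without Y replicate 2 or 3, and 0.43 or 0.22 without KY replicate 2 or 3. The ribosome median was 0.10, 0.40 or 0.08 without Y replicate 1, 2 or 3 and 0.46 without KY replicate 2.

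The total of 212 genes between KY and Y became 127 when only the libraries of Y and KY were fitted, 112 or 138 without Y replicate 1 or 2, and 131 without KY replicate 3. The split of 79 up and 133 down became 60 and 67 when only Y and KY were fitted. It became 52 and 60, or 61 and 77, without Y replicate 1 or 2, and 59 and 72 without KY replicate 3.

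Relative to the mean of K326 and Y, 51 genes were higher in KY and 148 lower (limma, Benjamini-Hochberg adjusted p below 0.05). In 5 genes KY was higher than both other materials and in 18 lower than both, by separate calls. The lower group holds transketolase Nitab4.5_0001329g0110, at 61.5 in KY against 504 in K326 and 554 in Y, and the mitochondrial carrier gene Nitab4.5_0010196g0040. The higher group, chosen after its values were seen, holds a Wax2-domain gene (Nitab4.5_0020701g0010; 0.857 in K326, 1.25 in Y, 16.9 in KY) and a SWEET sugar transporter gene (Nitab4.5_0007236g0030; 18.8, 19.0 and 44.8). It also holds a cytochrome c assembly protein gene (Nitab4.5_0001130g0160; 0.637, listed at 0, and 2.88), an F-box gene (Nitab4.5_0001863g0050; 0.13, 0.15 and 3.19) and Nitab4.5_0003602g0010, described as Unknown (listed at 0, 0.357 and 7.13). Median-of-ratios scaling gave 63 higher and 116 lower genes, and quantile normalization 60 and 100. The total of 199 became 453 without KY replicate 1, 86 without KY replicate 3, 100 or 104 without K326 replicate 1 or 2, and 108 or 131 without Y replicate 1 or 2.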

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

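Scaling and normalization, the mean of at least 5, and robust empirical Bayes were chosen after the data were seen; the other settings were planned. Of the named genes, 15 of 22 for Y minus K326, 10 of 17 for KY minus K326 and 10 of 15 for KY minus Y were called under each of up to 19 alternatives in which they were tested, and the estimates of none changed sign. The KY minus Y genes include dihydroneopterin aldolase, named by rule, which did not differ between KY and Y. The light-harvesting and dividing-cell lists kept their calls against K326 in all 19 alternatives for both Y and KY, as did chlorophyll biosynthesis for KY. Every called list kept the sign of its median under the 3 scalings. Without KY replicate 1 the dividing-cell list of KY minus Y reversed (-0.241); its median ranged from there to 0.428, the value without KY replicate 2. With camera's estimated correlation 0, 0 and 0 lists passed in Y minus K326, KY minus K326 and KY minus Y, and with fry 0, 0 and 0, against 7, 9 and 3 with the preset correlation; fry's mixed test, which asks for change in either direction, passed 16, 8 and 8. Without a filter on low values 4 lists passed for Y minus K326. With only the groups compared, KY minus Y gave 127 genes and 6 lists. Requiring a mean of at least 5, which tests fewer genes, gave 156, 60, 127 and 95 genes in the contrasts in the order of the processing account, an overlap of 39 genes, and 7 lists for KY minus Y. Deviations of same-numbered libraries from their group means correlated between -0.166 and 0.177, and 2 of 9 pairs were above 0.1. Differently numbered libraries were not compared in this way, so these values do not decide whether the replicate numbers pair the libraries. The fit with a replicate block gave 211, 85, 134 and 88 genes. Leaving out 1 library gave 176 to 450 genes for Y minus K326, 69 to 646 for KY minus K326, 112 to 307 for KY minus Y and 86 to 453 for KY against the mean; 5 to 9, 7 to 11 and 1 to 7 lists; overlaps of 60 to 180; and 62.4% to 68.6% of genes with KY between K326 and Y. Each highest gene count came without KY replicate 1. The cause of these shifts was not tested, apart from the fewer genes or libraries that some settings use. Read depth is unknown, so it could not be weighed for single genes.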

Other observations

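All tests in this part were chosen after the results were seen, except the regroupings of libraries. Annotation terms with at least 10 tested genes were compared by camera as an addition: of 700 terms, 28, 27 and 29 passed in Y minus K326, KY minus K326 and KY minus Y with the preset correlation, and 0 in each with an estimated correlation. Phosphate-induced protein 1 genes, of a family linked to cell expansion, stood lower in Y than in K326 (13 genes, median log2 difference -1.28, 3 called down, camera adjusted p = 7.33e-08; adjusted p = 0.999 with an estimated correlation). The DUF581 domain genes stood lower in KY than in K326 (21 genes, median -0.66, 3 called down, camera adjusted p = 1.62e-05; adjusted p = 0.998 with an estimated correlation), and small heat shock proteins with an alpha crystallin domain lower in KY than in Y (42 genes, median -0.87, 0 called by limma, 18 down and 2 up at an unadjusted p below 0.05, camera adjusted p = 0.00209; adjusted p = 0.996 with an estimated correlation). Aminoacyl-tRNA synthetase genes stood higher in KY than in Y (43 genes, median 0.22, 0 called by limma, 5 up at an unadjusted p below 0.05, camera adjusted p = 0.000182; adjusted p = 0.996 with an estimated correlation).

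Further single genes outside the naming rule, chosen after their values were seen, stand for no family. A manganese/iron superoxide dismutase gene (Nitab4.5_0002279g0090) had a mean of 6.56 in Y and 0.15 in K326 and was listed at 0 in all KY libraries (Y minus K326, limma adjusted p = 9.54e-05; KY minus Y, limma adjusted p = 0.000133). The SWEET sugar transporter gene Nitab4.5_0000849g0010 had means of 2.95 in K326, 11.1 in Y and 0.7 in KY (KY minus Y, limma adjusted p = 0.000994), and Nitab4.5_0007236g0030 had 18.8, 19.0 and 44.8 (KY minus Y, limma adjusted p = 0.0102).

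A group of 51 genes with a K326 mean of at least 5 lay at or below 0.5 in all 3 Y libraries, against 14 genes in the reverse direction. Whether the gene set stands closer to K326 than to Y is not known here, so the counts in these directions need not be comparable. Of the 51, 24 were also at or below 0.5 in all 3 KY libraries, 20 had a KY mean of at least 0.5 of the K326 mean, and 7 lay between. The KY count was 31. The identifiers carry a scaffold number, and some of these genes share a scaffold, which does not show that they are neighbours. On scaffold 0000826 all 6 tested genes with a K326 mean of at least 1 were at or below 0.5 in both Y and KY, and on the scaffold of the ChlI-domain magnesium chelatase gene all 4 were. On the scaffold of dihydroneopterin aldolase both were, the other being an Ataxin-2 domain gene. On the scaffold that holds the E2 and eIF-1A genes, 5 of 7 were in Y and 0 in KY. Among genes with a K326 mean of at least 1, 33 of the 60 at or below 0.5 in Y on the scaffolds of these genes shared 12 scaffolds, and 27 were the only ones on theirs. On 8 of the 12 all genes at this K326 level were near 0 in Y, and on the others, besides the 5 of 7 above, 2 of 5 (0000586), 2 of 10 (0000363) and 2 of 14 (0000147) were. On 17 of those 27 scaffolds, 56 other genes at this K326 level were not at or below 0.5 in all Y libraries, such as 10 of 11 on scaffold 0000914.

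Chance placement of unlinked genes was tested by a permutation test, with random draws from the 8293 genes with a K326 mean of at least 5: the 51 genes formed 18 same-scaffold pairs in Y, against at most 4 in 10000 draws, and the KY genes formed 11, against at most 3 (p = 1e-04 for both, the smallest these draws can give). Reads moved to a near-identical copy would keep the sum of both copies. In the 8 cases with a single tested partner of the same description, the median log2 ratio of the sum, Y over K326, was -1.43 (95% bootstrap interval -2.75 to -0.19). A complete transfer to these partners is therefore argued against for the 8 cases as a set. Partners were matched by description and not by sequence, so a transfer to some other copy was not tested. The interval treats the 8 pairs as independent, though some share scaffolds. A complete transfer to the partner is not argued against for single cases whose sum was nearly kept or higher. These were eIF-1A gene Nitab4.5_0003779g0110 (-0.19) and Nitab4.5_0005195g0030 (0.25), a glutamine amidohydrolase gene. The magnesium chelatase genes named above have unlike descriptions and were not among the 8 cases. The partners themselves were higher in Y by a median of 0.40 log2 units, with 6 of 8 higher. The one-sided permutation p was 2e-04 against random genes whose description 2 tested genes share, and it too treats the pairs as independent. An increased dose or activity of the partners would give such a rise, and so would a transfer of part of the reads. Of these partners 1 passed the limma test, eIF-1A copy Nitab4.5_0002262g0150, at 65.6 in K326 and 133 in Y. The 51 genes were at a median of 0.0839% of K326. How much a sequence in Y that differs from the reference would leave, from reads that still match, was not measured. Such a sequence and a missing or silent gene cannot be told apart, because reads were not analysed here. Why these genes were near 0 in Y, and why dihydroneopterin aldolase was at 0 in Y and KY, stays open, also because genes alone on scaffolds with other expressed genes need not share a cause with those that share a scaffold.

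KY replicate 1 correlated best with a K326 library, and without it the KY minus K326 count rose from 129 to 646. A K326 library labelled KY would carry the genes missing from KY, but of 26 genes at 5 or more in every K326 library and at or below 0.5 in KY replicates 2 and 3, 1 (3.85%) was above 0.5 in KY replicate 1. K326 RNA mixed into the library would leave a share of those genes, and their median level was 0.0622% of K326. The mean of the dividing-cell list was 1.10 log2 units higher in KY replicate 1 than in the higher of the other KY libraries, more than the range within K326 (0.85) or Y (0.53), which is consistent with a larger share of dividing or growing cells in that leaf sample. The list is mostly histones, which all leaf tissue expresses, and neither the age nor the position of the sampled leaves was used here, so this stays a hypothesis.

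Other splits of the libraries were counted for each contrast. The 3 libraries of each material allow 10 splits per pair of materials, too few for a share under 0.05. In Y minus K326 the real split gave 325 genes and the highest other 4, in KY minus K326 129 and 2, and in KY minus Y 212 and 1, so that in each contrast 1 of 10 splits, the real one, gave as many genes. For KY against the mean of K326 and Y, 1 of 100 regroupings of the 9 libraries gave as many genes as the real 199, namely the real one. The highest other regrouping gave 176, with the Y libraries in the place of KY.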
